A study of Mus musculus with 6 samples.

How the data were processed

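RNA-seq libraries had been made from total RNA of osteoblasts with a SMARTER mRNA-seq kit. The cells were derived from mesenchymal stem cells of mouse tibial and femoral marrow, at day 7 of osteogenic culture. Of the 6 libraries, 3 were labelled control and 3 verapamil, and each column of the count table matched 1 library through its label. The table was deposited as 1 estimated count per gene and library, per the file headers a read count, not scaled to depth or gene length. It held 17491 genes, all typed as mRNA, of which 67.7% of the values were not whole numbers, and no gene had a summed count under 1. The build named in the submitters' processing notes is GRCm38, also called mm10. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

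Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 13366 genes for testing and took out 4125. Library totals ran from 18.2 M to 21.7 M. Library composition was scaled with TMM factors. Verapamil was compared with control, the 1 comparison of the design, with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood fit with robust estimation and the Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is the one implied by the F statistic of that test, the absolute log2 fold change over the square root of F. Log2 CPM values for principal components and list tests used a prior count of 2. Coordinates came from the RefSeq gene table for GRCm38, matched on Entrez ID for 17360 genes, of which 17347 had the same symbol. Transcript length and GC content came from the longest GENCODE transcript of each symbol.

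Gene lists for pathways, cell types and library quality were written before the data were examined, as were the tests, the alternatives and the rule for naming genes, save where stated. Pathway and cell type lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01. They were tested again with a correlation estimated from these libraries and with fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes. The lists covered osteoblast differentiation and mineralisation, the thioredoxin-interacting protein and ChREBP axis, glycolysis, calcium channel subunits, the immediate-early and calcium-calcineurin response, osteoblast-derived regulators of osteoclasts, Wnt, BMP and TGF-β, and MAPK feedback targets, NF-κB, interferon, fibrillar collagens, matrix-degrading enzymes, cholesterol, fatty acids, lysosome and autophagy, stress of the endoplasmic reticulum, NRF2, hypoxia, oxidative phosphorylation, the cell cycle and contractile genes. Cell type lists covered osteocytes, mesenchymal stem cells, adipocytes, chondrocytes, macrophages, osteoclasts, neutrophils, endothelial cells, lymphocytes, mast cells and erythroid cells. Quality lists were sex-linked and ribosomal protein genes. Mitochondrially encoded genes were not analysed here.

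Named genes were those past the test whose 3 verapamil values all lay above or all below the 3 control values, with a mean of at least 5 CPM. Predicted genes, clones and pseudogenes were passed over. The 10 largest rises and the 10 largest falls were taken, then up to 4 members past the test with the largest change from each list, or, where none passed, up to 2 members with the highest mean. Txnip, Mlxipl, Arrdc4, Runx2, Sp7, Alpl, Col1a1, Bglap, Bglap2, Spp1, Ibsp, Pparg, Tnfsf11, Tnfrsf11b and Cacna1c were taken whether or not they passed. Members beyond this rule were chosen after their values were seen, whether or not the text marks them so. The values of some genes that the rule or the lists take in are not reported here.

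The gene test was tested on simulated counts for verapamil against control, with 13366 genes, 10 draws and 100 genes changed at each fold in each draw. It recovered 66.6% of genes changed 1.5-fold and 86.1% of those changed 2-fold, and 8.73% of its calls were false. The simulation gave each gene the same spread in both groups. In the last draw, camera at its preset correlation called a list of 25 genes shifted by -0.5 and none of 30 lists left as they were. Simulated genes varied independently, so this does not test camera on lists whose genes move together. The correlation estimated for the real lists reached 0.872, in the hypoxia response. Alternatives were other scaling factors (DESeq2 size factors, upper quartile, library totals alone), no filter and a filter of at least 5 CPM in 3 libraries, the test of DESeq2 1.42.0, limma-voom, other thresholds, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were counts without rounding, limma-voom with a weight per library, and the hypoxia and glycolysis counts without control replicate 2.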

Results

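RNA-seq was used to ask how verapamil, a blocker of L-type voltage-gated calcium channels, alters gene expression in osteoblasts. Mesenchymal stem cells of mouse bone marrow had been kept in osteogenic medium with dexamethasone, β-glycerophosphate and ascorbic acid up to day 7. The data comprised 3 control libraries and 3 verapamil libraries. Neither the verapamil dose nor the length of exposure is given in the labels. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Estimated counts summed to 21.7 M, 20.1 M and 21.7 M reads in control replicates 1, 2 and 3, and to 18.2 M, 21.6 M and 21.7 M in verapamil replicates 1, 2 and 3. Between 15757 and 15962 of the 17491 listed genes were detected in each library, and the 10 most abundant genes took 7.76% to 9.89% of the counts. Gene levels are given as TMM-normalised CPM, mean ± SD with n = 3 per group, and log2 fold changes of verapamil over control with their standard error (SE). Adjusted p values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera with the same adjustment.

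Both groups separated along the first principal component of log2 CPM, which held 66.2% of the variance. Control replicates 1, 2 and 3 lay at -25.7, -41.1 and -11.2 on it, and verapamil replicates 1, 2 and 3 at 26.5, 29.8 and 21.7. Control libraries were farther apart from each other than verapamil libraries. The biological coefficient of variation was 12.4% among the controls and 4.46% among the verapamil libraries. Counts of replicate pairs differed by more than sampling noise in every case, with chi-square values per degree of freedom of 12.1 to 47.8 for control pairs and 3.49 to 6.0 for verapamil pairs. Control replicate 2 stood farthest from the verapamil libraries. Its hypoxia response genes averaged 6.44 log2 CPM, against 5.83 and 5.33 in control replicates 1 and 3 and 4.73 to 4.90 in the verapamil libraries.

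Verapamil cultures held less RNA for bone matrix and osteoblast proteins than control cultures, and more RNA for macrophage, lysosomal and antioxidant proteins. Col1a1, the main chain of bone collagen, made up 1.46%, 2.07% and 1.42% of the counts in the controls and 0.529%, 0.515% and 0.617% in the verapamil libraries. Lyz2, the lysozyme of macrophages and neutrophils, went the other way, from 0.581%, 0.407% and 0.635% to 1.15%, 1.24% and 1.06%. Of 13366 genes tested, 2055 were higher and 2180 lower with verapamil, 4235 in all. Among these, 157 were higher and 383 lower by at least 1 on the log2 scale. The groups did not overlap in 6626 genes (49.6%), where chance gives 10%. Of the changed genes, 48.5% were higher, and 63.7% were when libraries were scaled by their totals alone. The count of changed genes was 2671 without control replicate 1 and 2249, 2236 and 2625 without verapamil replicates 1, 2 and 3. Those higher numbered 1216 without control replicate 1 and 1027, 1010 and 1232 without verapamil replicates 1, 2 and 3, and those lower 1222, 1226 and 1393 without verapamil replicates 1, 2 and 3.

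Among genes with a mean of at least 5 CPM whose groups did not overlap, the largest rise was that of Marco, a scavenger receptor of macrophages (Entrez 17167, chromosome 1, 120474538 to 120505024 in GRCm38). It rose from 4.77 ± 1.45 to 41.2 ± 9.59 CPM, by 3.10 ± 0.25 SE on the log2 scale (adjusted p = 4.40e-04). Chil3, a chitinase-like protein secreted by macrophages, rose from 146.5 ± 10.3 to 783 ± 53.9 CPM (2.42 ± 0.08 SE, adjusted p = 1.30e-05). The β-glucan receptor Clec7a rose by 1.89, the macrophage-secreted protein Cd5l by 1.72 and the iron exporter Slc40a1 by 1.71 on the log2 scale. Also among the 10 largest rises were Gsta4 (1.85), Mmp8 (1.79), Vipr2 (1.76), Stra6l (1.73) and Klhl4 (1.71). The call of Gsta4 was lost without verapamil replicate 2 (adjusted p = 0.0510). At the other end, Dmp1, a matrix phosphoprotein of late osteoblasts and osteocytes (Entrez 13406, chromosome 5, 104197575 to 104214102), fell from 79.7 ± 20.8 to 3.65 ± 0.861 CPM, with a log2 fold change of -4.43 ± 0.27 SE (adjusted p = 2.17e-04). Egln3, a prolyl hydroxylase induced by low oxygen, fell from 39.99 ± 24.4 to 3.43 ± 0.513 CPM (-3.54 ± 0.53 SE, adjusted p = 0.00451). The lactate exporter Slc16a3 fell by 2.44 and the collagen gene Col15a1 fell by 2.42. Megf10 (-3.33), Mgarp (-3.28), Cox4i2 (-2.93), Nxph4 (-2.61), Sema4f (-2.53) and Krt19 (-2.47) completed the 10 largest falls. Nxph4 was no longer past the test without control replicate 2 or without verapamil replicates 1, 2 or 3 (adjusted p = 0.0504 to 0.0794), nor was Krt19 without control replicate 1 or verapamil replicates 1, 2 or 3 (adjusted p = 0.0529 to 0.121). With all libraries, neither passed without the low-count filter (adjusted p = 0.0740 and 0.122), nor Krt19 by limma-voom (adjusted p = 0.0958).

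**Figure D1:**
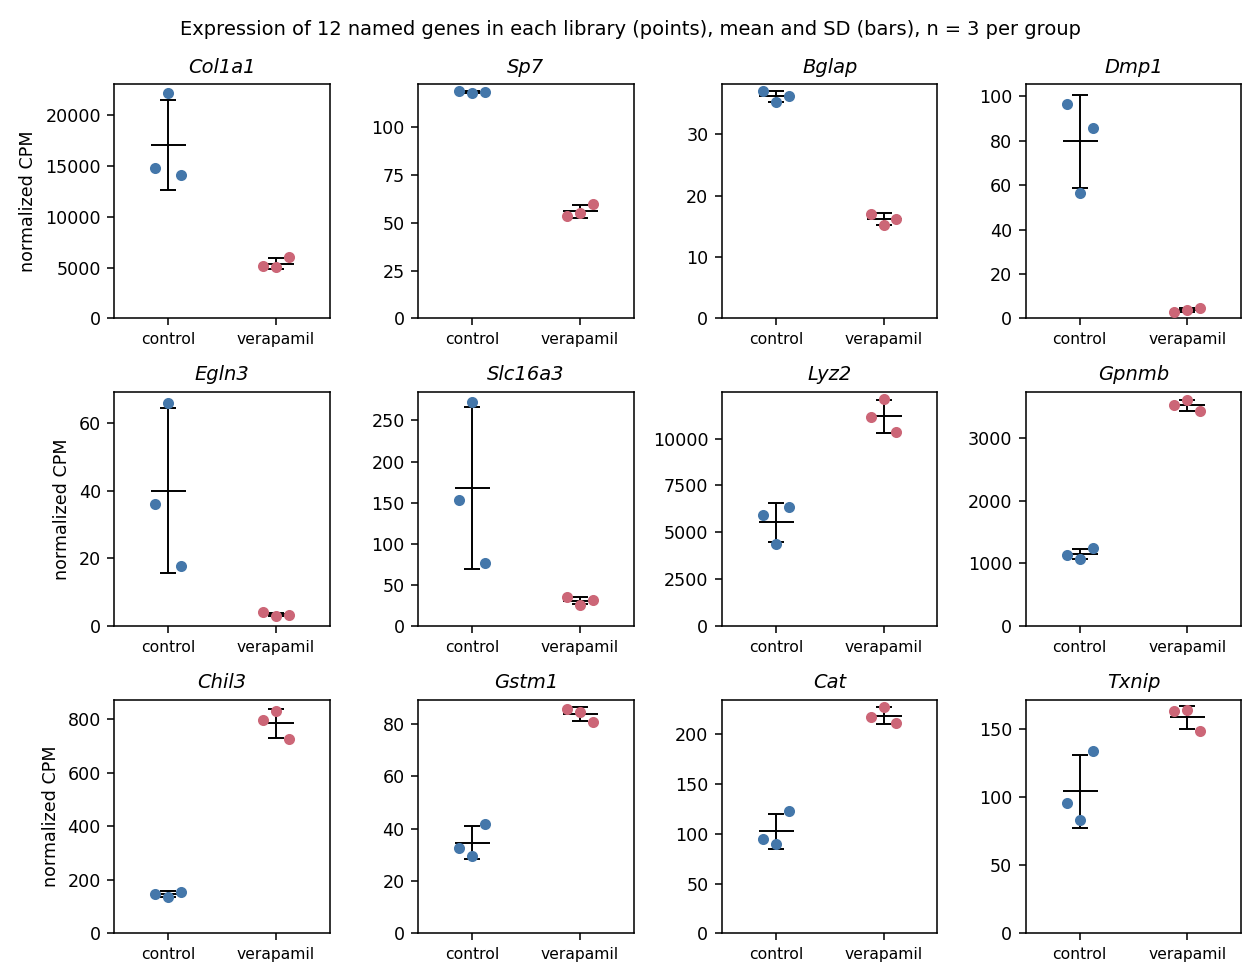
Normalised CPM of 12 named genes in each library (points), with the mean and SD per group (bars, n = 3), control against verapamil. Dmp1 averaged 79.7 CPM in control and 3.65 CPM in verapamil libraries and Chil3 146.5 and 783 CPM.

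Genes were grouped into lists for pathways, cell types and quality that were chosen before the data were examined. Some genes stand on several lists, so the lists are not independent. Of 30 lists tested by camera, 16 were lower and 11 higher with verapamil at its preset correlation of 0.01. With a correlation estimated from these libraries, 0 lists passed (10 did at an unadjusted p under 0.05, and fry called 25), and the smallest adjusted p was 0.0829. Of the 141 named genes tested, 133 passed, a share largely fixed by the naming rule, which took most of them because they passed. Of these, 86 passed without each library in turn.

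Osteoblast genes fell as a group. In the list for osteoblast differentiation and mineralisation, 23 of 27 tested members fell, 1 rose and 3 did not pass (23 fell and 1 rose adjusted over the list alone). Their median log2 fold change was -0.95. Camera gave adjusted p = 1.70e-11, and adjusted p = 0.0829 with an estimated correlation. Sp7, a transcription factor needed for osteoblast formation (Entrez 170574, chromosome 15, 102356603 to 102367035), fell from 118 ± 0.444 to 55.9 ± 3.27 CPM (-1.08 ± 0.06 SE, adjusted p = 7.08e-05). Runx2, the early regulator of the lineage, fell from 105 ± 5.88 to 74.0 ± 1.96 CPM (-0.50 ± 0.06 SE, adjusted p = 7.98e-04). Col1a1 (Entrez 12842, chromosome 11, 94936224 to 94953042) fell from 17067 ± 4439 to 5387 ± 539.6 CPM (-1.66 ± 0.19 SE). The morphogen Bmp2 (-2.22), the osteoblast membrane protein gene Ifitm5 (-2.15), Ibsp (-0.98) and Alpl, which encodes the phosphatase of mineralising cells (-0.75), also fell. Osteocalcin genes fell as well, Bglap from 36.2 ± 0.851 to 16.2 ± 0.910 CPM and Bglap2 from 32.5 ± 3.97 to 16.9 ± 1.93 CPM. These neighbours are near-identical copies, so how their reads were shared is uncertain. Spp1, encoding osteopontin, was at 9785 ± 1474 and 11651 ± 1285 CPM (0.25 ± 0.14 SE, adjusted p = 0.217). Dlx5 (-0.09) did not pass either, and the 1 member that rose was the adhesion molecule Cadm1 (0.81). Both were chosen after their values were seen. Mean expression of the list was at least 6.94 log2 CPM in each control and at most 6.07 in each verapamil library. Over the same libraries, macrophage and monocyte markers had a median log2 fold change of 0.58.

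Extracellular matrix genes also fell. Among fibrillar collagens and matrix assembly genes, 28 of 33 fell and 5 did not pass (29 fell adjusted over the list alone), with a median of -0.99. Camera gave adjusted p = 4.16e-14, and adjusted p = 0.146 with an estimated correlation. Examples were Col6a3 (2444 ± 378 to 778 ± 103 CPM, -1.65 ± 0.14 SE), Eln, which encodes elastin (-2.03), and the collagen prolyl hydroxylase P4ha2 (-1.57). The call of P4ha2 was lost without verapamil replicates 1, 2 or 3 (adjusted p = 0.0636 to 0.0796) and without the low-count filter (adjusted p = 0.0789). Of 17 matrix-degrading enzymes and their inhibitors, 13 fell, 2 rose and 2 did not pass (13 and 2 adjusted over the list alone), with a median of -0.61. Camera gave adjusted p = 2.29e-04, and adjusted p = 0.146 with an estimated correlation. The count that fell was 8 without control replicate 1 and 7 without verapamil replicate 2. The inhibitors Timp1 (-1.29) and Timp3 (-1.54) fell, as did the stromelysin Mmp10 (-2.18). Mmp8, the collagenase of neutrophils, rose from 3.30 ± 0.221 to 11.5 ± 1.35 CPM, and Adamts5, named after its value was seen, rose by 0.30. Timp3 was not past the test without verapamil replicate 2 (adjusted p = 0.0533), nor Mmp10 without control replicate 1 or verapamil replicate 2 (adjusted p = 0.0593 and 0.0701). Macrophage markers, at a median of 0.58, moved the opposite way in these libraries.

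Markers of related skeletal cells were mostly lower. For osteocyte markers, 4 of 6 fell and 2 did not pass (5 fell adjusted over the list alone), with a median of -0.76 (camera adjusted p = 0.0204, and adjusted p = 0.154 with an estimated correlation). They were Dmp1, Phex (-1.24), Ptprz1 (-1.09) and Pdpn (-0.44), and the count was 1 without control replicate 1 and 2 without each of verapamil replicates 1, 2 and 3. Without control replicate 1 or verapamil replicate 1 none of Phex, Ptprz1 and Pdpn passed, nor did Phex and Pdpn without verapamil replicate 2 or Ptprz1 and Pdpn without verapamil replicate 3 (adjusted p = 0.0516 to 0.0975). Among chondrocyte markers, 5 of 10 fell and 5 did not pass (5 fell adjusted over the list alone), with a median of -0.82 (camera adjusted p = 6.32e-04, and adjusted p = 0.0829 with an estimated correlation). The cartilage link protein gene Hapln1 fell from 3.67 ± 0.283 to 0.418 ± 0.260 CPM (-3.09 ± 0.32 SE), and Col2a1, Col10a1 and Comp fell by 2.22, 1.36 and 0.85. Sox9 (-0.78), named after its value was seen, also fell. Without verapamil replicate 2, Col2a1 was at adjusted p = 0.0506. Mesenchymal stem and progenitor cell markers had 8 of 16 members lower, 2 higher and 6 not past the test (8 and 2 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.0175, and adjusted p = 0.150 with an estimated correlation). Nt5e, encoding the surface antigen CD73, fell from 38.2 ± 5.12 to 13.1 ± 0.302 CPM (-1.54 ± 0.10 SE), and Nes (-1.55) and Thy1 (-0.96) fell too. Cxcl12 (0.57) and Vcam1 (0.28) were higher and were named after their values were seen, and without control replicate 1 or any 1 of verapamil replicates 1, 2 and 3 neither passed (adjusted p = 0.0887 to 0.154). Without control replicates 1 or 2 or any 1 of the verapamil replicates, the fall of Grem1 (-1.06) did not pass (adjusted p = 0.0613 to 0.0990), nor did it without the low-count filter (adjusted p = 0.0753). Macrophage markers stood at a median of 0.58 in this comparison.

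**Figure D2:**
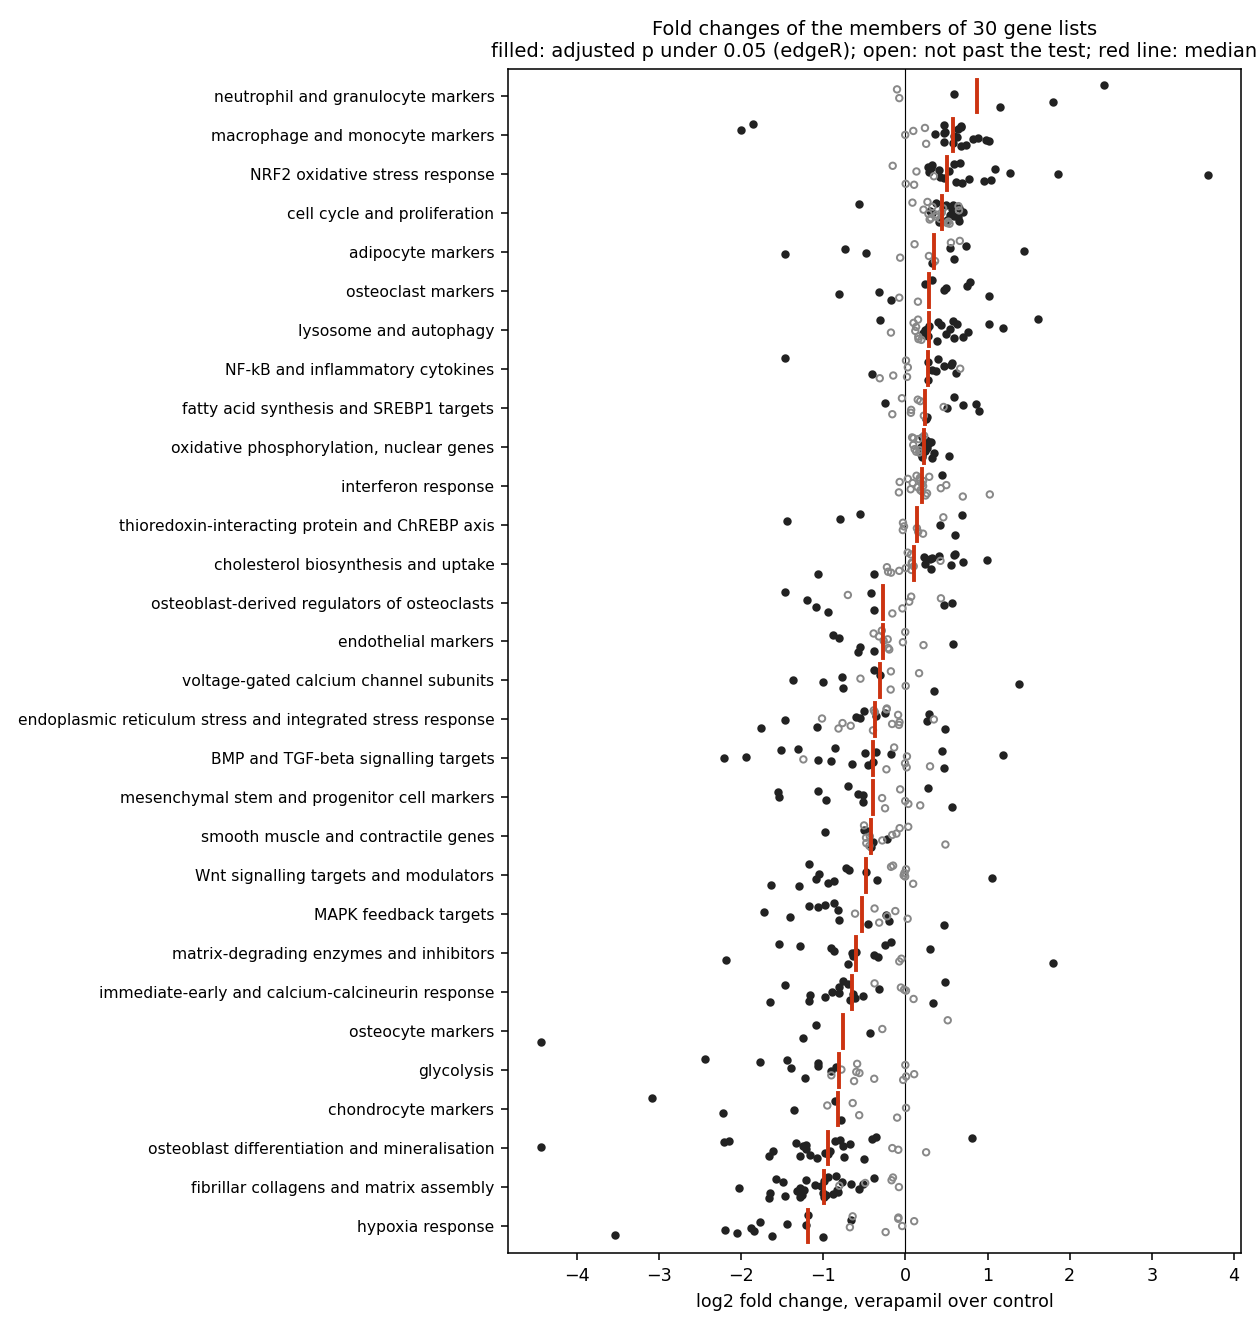
Log2 fold change, verapamil over control, of every tested member of 30 gene lists (filled points, past edgeR's test at an adjusted p under 0.05; open points, not past), with the list median as a red line. Medians ran from -1.18 for the hypoxia response to 0.87 for neutrophil and granulocyte markers.

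Signalling genes of bone cells were lower in several lists. Of 19 Wnt targets and modulators, 11 fell, 1 rose and 7 did not pass (11 and 1 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 3.38e-04, and adjusted p = 0.0829 with an estimated correlation). The feedback inhibitor Axin2 fell from 20.4 ± 3.29 to 8.33 ± 1.09 CPM, and Tcf7 (-1.64) and Wnt10b (-1.17) fell too. Dkk2 (1.05), a Wnt antagonist named after its value was seen, rose, but not without control replicate 1 or verapamil replicates 1 or 2 (adjusted p = 0.0592 to 0.0686). The number of Wnt genes that fell was 5, 6 and 7 without verapamil replicates 1, 2 and 3. Of 23 BMP and TGF-β genes, 13 fell, 3 rose and 7 did not pass (14 and 3 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 8.09e-04, and adjusted p = 0.0829 with an estimated correlation). Bmp2 fell from 28.8 ± 6.81 to 6.19 ± 0.737 CPM, Bmp3 fell by 1.94, and the TGF-β target Ccn2 fell by 1.31. Those that rose were Bmp6 (1.18), Id2 (0.47) and Tgfbi (0.44), named after their values were seen. Only 1 of these 3 passed without control replicate 1, control replicate 2 or verapamil replicate 2. MAPK feedback targets, read as a trace of growth factor signalling, had 11 of 18 members lower, 1 higher and 6 not past the test (14 and 1 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 3.87e-05, and adjusted p = 0.226 with an estimated correlation). Etv4 (-1.73), Spry4 (-1.40) and Myc (-1.07) fell, Dusp1 (0.47, named after its value was seen) rose, and 7 members fell without verapamil replicate 2 or 3. Macrophage markers had a median of 0.58 in the same libraries, with 17 of 23 higher.

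Calcium-responsive and calcium channel genes were measured because of the drug's target, in libraries whose macrophage markers had a median of 0.58. In the immediate-early and calcium-calcineurin list, 15 of 22 members fell, 2 rose and 5 did not pass (16 and 2 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 6.42e-05, and adjusted p = 0.204 with an estimated correlation). Egr3 fell from 34.98 ± 0.362 to 15.7 ± 0.612 CPM (-1.16 ± 0.06 SE, adjusted p = 7.08e-05), and Fosb fell by 1.65. Ptgs2 (-1.47) and Fosl1 (-1.18) fell too, but not without control replicates 1 or 2 or any 1 of the verapamil replicates (adjusted p = 0.0594 to 0.142). Neither passed without the low-count filter (adjusted p = 0.0867 and 0.0924), nor Ptgs2 by limma-voom (adjusted p = 0.0634). The members that rose were Atf3 (0.48) and Fos (0.33), named after their values were seen, of which Fos did not pass without control replicate 1 or verapamil replicates 1 or 3 (adjusted p = 0.0594 to 0.0912). The number that fell was 9 without control replicate 1 and 9, 8 and 9 without verapamil replicates 1, 2 and 3. Of 13 calcium channel subunits, 6 fell, 2 rose and 5 did not pass (6 and 2 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.0294, and adjusted p = 0.154 with an estimated correlation). Without control replicate 3 that list was at camera adjusted p = 0.0629. Cacna1c, the pore-forming subunit that verapamil blocks in heart and vessels, fell from 25.5 ± 0.575 to 14.97 ± 1.42 CPM (-0.76 ± 0.08 SE, adjusted p = 6.13e-04). The T-type subunit Cacna1g (-0.999) and the β subunit Cacnb2 (-0.77) fell. Cacna1h (-1.37) fell, but not without verapamil replicates 1, 2 or 3 (adjusted p = 0.0557 to 0.0729). Cacna1f was at 0.336 ± 0.0735 and 0.891 ± 0.173 CPM (1.39 ± 0.32 SE), a rise not past the test without control replicate 1 or verapamil replicates 2 or 3 (adjusted p = 0.0527 to 0.0605). Cacna1a (0.34), named after its value was seen, did not pass without control replicate 1 or any 1 of the verapamil replicates (adjusted p = 0.0593 to 0.113).

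Txnip, encoding the thioredoxin-interacting protein (Entrez 56338, chromosome 3, 96557957 to 96561857), was higher with verapamil, at 104 ± 26.7 CPM in control and 159 ± 8.52 CPM in verapamil libraries (0.61 ± 0.17 SE, adjusted p = 0.0319). That call was lost without control replicate 1 or 2 and without verapamil replicates 1, 2 or 3 (adjusted p = 0.0673 to 0.0983), and without the low-count filter (adjusted p = 0.0577). Its relative Arrdc4 was at 151 ± 35.98 and 175 ± 14.8 CPM (0.21 ± 0.17 SE, adjusted p = 0.367) and passed only without control replicate 3 (adjusted p = 0.0377). Mlxipl, the carbohydrate response factor upstream of both, had estimated counts of 2 to 6.87 per library and was not tested. In the list for this axis, 3 of 13 members rose, 3 fell and 7 did not pass (3 and 3 adjusted over the list alone). Its median was 0.14, its mean -0.02, and camera gave adjusted p = 0.528 in the upward direction. Fry called the list higher (adjusted p = 0.0280), and without control replicate 2 the median was 0.05. The pentose phosphate enzyme gene G6pdx (0.68) rose, as did Txnrd1 (0.42, named after its value was seen), while the glucose transporters Slc2a1 (-1.44) and Slc2a3 (-0.80) and the transcription factor Klf10 (-0.55, likewise) fell. The fall of Slc2a1 was lost without verapamil replicates 1, 2 or 3 (adjusted p = 0.0674 to 0.0873) and without the low-count filter (adjusted p = 0.0896). Without control replicate 3, 5 members rose.

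With macrophage markers at that same median of 0.58, osteoblast-derived regulators of osteoclasts moved both ways, with 6 of 14 lower, 2 higher and 6 not past the test (7 and 2 adjusted over the list alone), a median of -0.27 and camera adjusted p = 0.0503. Tnfrsf11b, the decoy receptor osteoprotegerin, fell from 94.3 ± 11.5 to 48.9 ± 2.57 CPM (-0.95 ± 0.09 SE, adjusted p = 3.87e-04), and Wnt5a fell by 1.20. Tnfsf11, its ligand RANKL, was at 3.82 ± 0.664 and 3.41 ± 0.570 CPM (-0.16 ± 0.19 SE, adjusted p = 0.550). The cytokine gene Il11 was at 0.852 ± 0.188 and 0.391 ± 0.0670 CPM, a fall not past the test without control replicates 1 or 2 or any 1 of the verapamil replicates (adjusted p = 0.0647 to 0.105), nor past that of DESeq2 with all libraries (adjusted p = 0.122). Camera called the list lower without control replicate 1 (adjusted p = 0.0270) and without verapamil replicate 2 (adjusted p = 0.0363), and fry called it lower with all libraries (adjusted p = 0.00182). The members that rose, Cxcl12 (0.57) and Ccl2 (0.47), were named after their values were seen. Neither passed without verapamil replicate 1 or 2, nor Cxcl12 without control replicate 1 or verapamil replicate 3 (adjusted p = 0.0647 to 0.154).

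Some genes of the response to low oxygen and of glycolysis were lower with verapamil, and the controls differed widely in them. Fry called neither list (adjusted p = 0.0532 for hypoxia and 0.135 for glycolysis). In the hypoxia response list, 12 of 19 fell and 7 did not pass (13 fell adjusted over the list alone), with a median of -1.18 (camera adjusted p = 6.42e-05, and adjusted p = 0.402 with an estimated correlation). The mitophagy receptor gene Bnip3 fell from 322 ± 172 to 77.5 ± 6.80 CPM (-2.05 ± 0.39 SE, adjusted p = 0.00991). Carbonic anhydrase Car9 (-2.20) and the oxidoreductase Ero1a (-1.88) fell, with calls lost without any 1 of the verapamil replicates, for Car9 also without control replicate 1 and for Ero1a without control replicate 2 (adjusted p = 0.0618 to 0.128). Neither passed without the low-count filter (adjusted p = 0.109 and 0.0744), nor Car9 by limma-voom (adjusted p = 0.0782). The count was 6 and 7 without verapamil replicates 2 and 3, and 11 without control replicate 2. Glycolysis had 9 of 20 members lower and 11 not past the test (9 fell adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.00134, and adjusted p = 0.472 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell from 162 ± 63.9 to 47.4 ± 5.69 CPM (-1.77 ± 0.29 SE, adjusted p = 0.00626). Pgk1 (-1.39) fell, but not without control replicates 1 or 2 or any 1 of the verapamil replicates (adjusted p = 0.0646 to 0.105), nor without the low-count filter (adjusted p = 0.0982). Counts for glycolysis were 5, 4 and 14 without control replicates 1, 2 and 3, and 2 without each verapamil replicate. Without the low-count filter 3 members fell, and without control replicate 2 the median was -0.42. Mean expression of that list was 7.91, 8.51 and 7.41 log2 CPM in control replicates 1, 2 and 3, and 7.11 to 7.27 in the verapamil libraries. Both lists were highest in control replicate 2, the library farthest from the verapamil group, and macrophage markers had a median of 0.58.

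**Figure D3:**
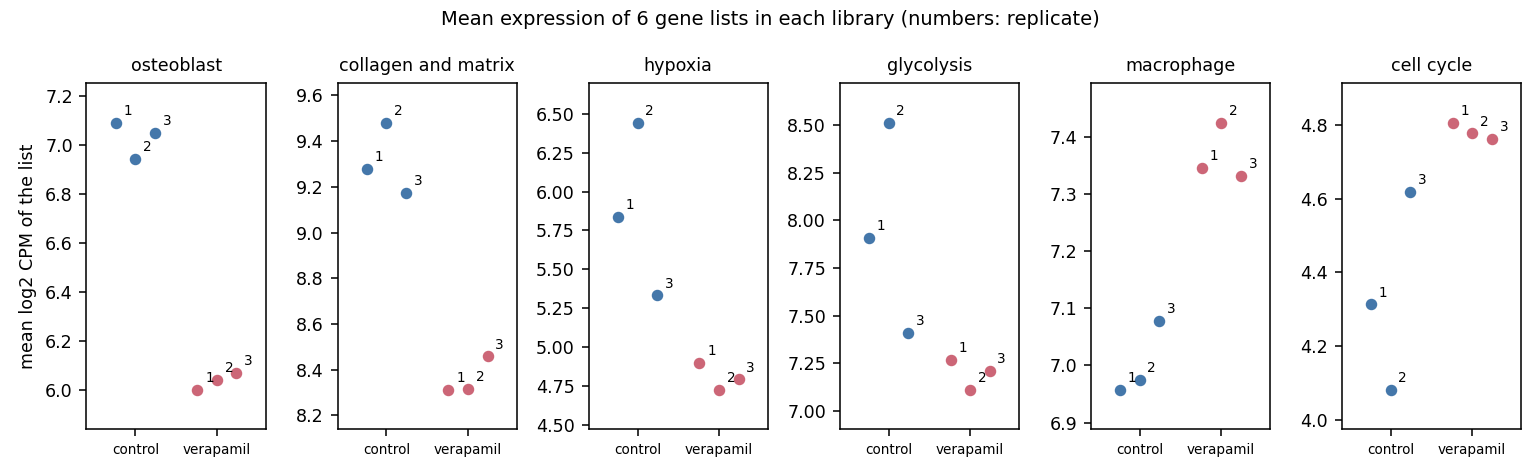
Mean log2 CPM of 6 gene lists in each library, control against verapamil, with replicate numbers beside the points and a separate vertical scale for each list. Control replicate 2 was highest for hypoxia (6.44) and glycolysis (8.51) and lowest for the cell cycle (4.08), and no list had a control value inside the range of the verapamil values.

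Cell cycle, stress and contractile genes varied with the same control libraries, and macrophage markers had a median of 0.58. Of 32 cell cycle genes, 14 rose, 1 fell and 17 did not pass (24 and 1 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 1.58e-06, and adjusted p = 0.382 with an estimated correlation). The mitotic kinesin gene Kif20a rose from 17.6 ± 3.31 to 28.7 ± 0.872 CPM (0.70 ± 0.12 SE), and the mitotic kinase gene Plk1 rose by 0.64, though not without control replicate 1 or verapamil replicate 1 (adjusted p = 0.0505 and 0.0532). Rrm2 (-0.57), named after its value was seen, fell but did not pass without control replicate 1 or any 1 of the verapamil replicates (adjusted p = 0.0544 to 0.0812). The number that rose was 3 and 29 without control replicates 1 and 3, and 3, 5 and 7 without verapamil replicates 1, 2 and 3. List means were 4.31, 4.08 and 4.62 log2 CPM in control replicates 1, 2 and 3 against 4.76 to 4.81 with verapamil. For endoplasmic reticulum stress and the integrated stress response, 8 of 25 fell, 3 rose and 14 did not pass (14 and 3 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.00707, and adjusted p = 0.533 with an estimated correlation). The chaperone gene Hsp90b1 fell from 1231 ± 244 to 814 ± 38.8 CPM (-0.60 ± 0.13 SE), with a call lost without verapamil replicates 1 or 2 (adjusted p = 0.0566 and 0.0533). Vldlr (-1.47) fell, but not without any 1 of the verapamil replicates (adjusted p = 0.0556 to 0.0730), nor without the low-count filter (adjusted p = 0.0698). Without control replicates 1 and 3 the number that fell was 3 and 18. Without verapamil replicates 1, 2 and 3 it was 1, 1 and 4. With all libraries it was 16 by DESeq2 and 6 without the low-count filter. The median was -0.23 without control replicate 2. Atf3 (0.48), Sdf2l1 (0.29) and Ddit4 (0.26), named after their values were seen, rose. Only 1 of these passed without control replicate 1 or without any 1 of the verapamil replicates. Smooth muscle and contractile genes had 6 of 17 lower and 11 not past the test (11 fell and 1 rose adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.00366, and adjusted p = 0.329 with an estimated correlation). Smtn fell from 149 ± 51.1 to 75.4 ± 2.51 CPM, and Acta2 was at 1121 ± 193 and 840.1 ± 54.8 CPM (-0.42 ± 0.12 SE, adjusted p = 0.0321). Neither passed without any 1 of the verapamil replicates, nor Acta2 without control replicate 1 (adjusted p = 0.0533 to 0.123). Adjusted over the list alone, the 1 that rose was Myh11 (0.49), chosen after its value was seen. The count that fell was 1 without control replicate 1 or verapamil replicate 2, and none without verapamil replicate 1 or 3. It was 9 without control replicate 2 or 3. With all libraries it was 3 with library totals alone and 9 by DESeq2. The contractile median was -0.27 without control replicate 2.

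Macrophage genes were higher in the verapamil cultures. In the list of macrophage and monocyte markers, 17 of 23 rose, 2 fell and 4 did not pass (17 and 2 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 7.43e-07, and adjusted p = 0.176 with an estimated correlation). Lyz2 rose from 5536 ± 1039 to 11197 ± 883 CPM (1.02 ± 0.15 SE, adjusted p = 0.00213) and Lyz1 from 427 ± 52.5 to 839 ± 95.7 CPM (0.98 ± 0.11 SE). These lysozyme genes are close copies, so their separate levels are uncertain. The members that fell were H2-Ab1, a class II antigen-presenting chain, from 17.8 ± 9.72 to 4.43 ± 0.746 CPM (-2.00 ± 0.41 SE), and Ccr2, the chemokine receptor of inflammatory monocytes, from 0.7501 ± 0.215 to 0.203 ± 0.0584 CPM (-1.85 ± 0.40 SE). Without verapamil replicate 2, H2-Ab1 was at adjusted p = 0.0517. Csf1r (0.25), Aif1 (0.24) and Cd74 (0.10), chosen after their values were seen, did not pass, nor did Mrc1 (adjusted p = 0.982). Osteoclast markers had 7 of 12 members higher, 3 lower and 2 not past the test (7 and 3 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0297, and adjusted p = 0.154 with an estimated correlation). Without control replicate 3 the list was at camera adjusted p = 0.123. The receptor gene Trem2 rose from 96.8 ± 3.50 to 166 ± 1.64 CPM and the proton pump gene Tcirg1 from 91.7 ± 3.01 to 154 ± 8.44 CPM. Itgb3, the integrin of attached osteoclasts, fell from 29.96 ± 1.83 to 17.2 ± 0.942 CPM. Nfatc1 (-0.32) and Ctsk (-0.18), named after their values were seen, fell, but neither passed without control replicate 1 or any 1 of the verapamil replicates (adjusted p = 0.0579 to 0.166). Neutrophil and granulocyte markers had 4 of 6 higher and 2 not past the test (4 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.00389, and adjusted p = 0.131 with an estimated correlation). They were Chil3, Mmp8, Csf3r (0.59) and S100a8. The last was at 0.402 ± 0.182 and 0.913 ± 0.223 CPM and did not pass without control replicate 2 or 3 or any 1 of the verapamil replicates (adjusted p = 0.0618 to 0.159). With all libraries its call was lost with DESeq2 size factors (adjusted p = 0.0501), without the low-count filter (0.0599), by DESeq2 (0.117) and by limma-voom with library weights (0.0786), each of which left 3 members higher. Without control replicate 3 the list was at camera adjusted p = 0.0502.

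Lysosomal genes rose alongside the macrophage markers, whose median was 0.58. Among lysosome and autophagy genes, 19 of 28 rose, 1 fell and 8 did not pass (19 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 4.83e-08, and adjusted p = 0.0829 with an estimated correlation). The membrane glycoprotein gene Gpnmb rose from 1148 ± 84.1 to 3517 ± 86.5 CPM (1.62 ± 0.09 SE, adjusted p = 7.08e-05). Lipa, the acid lipase, rose from 153 ± 22.7 to 347 ± 24.7 CPM (1.18 ± 0.11 SE), and the proton pump subunit Atp6v0d2 rose by 1.02. Wipi1 (-0.31), named after its value was seen, fell. Of 17 NF-κB and inflammatory cytokine genes, 9 rose, 2 fell and 6 did not pass (10 and 2 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0294, and adjusted p = 0.154 with an estimated correlation). The feedback inhibitor Tnfaip3 rose from 18.1 ± 0.327 to 27.7 ± 1.31 CPM (0.61 ± 0.07 SE), and 3 and 4 genes rose without verapamil replicates 1 and 2. Ptgs2 (-1.47) and Relb (-0.41, named after its value was seen) fell, and neither passed without control replicate 1 or any 1 of the verapamil replicates (adjusted p = 0.0512 to 0.108), nor Ptgs2 without control replicate 2 (adjusted p = 0.142). Without control replicate 3 the list was at camera adjusted p = 0.0877. Interferon response genes had 1 of 22 members higher, Ifi35 (0.44), and 21 not past the test, with a median of 0.20. Adjusted over the list alone, 0 passed by edgeR's test, where 4 had an unadjusted p under 0.05 and DESeq2 called 2 over all genes. Camera gave adjusted p = 0.0354, adjusted p = 0.586 with an estimated correlation, and 0.460 and 0.240 without control replicate 3 and verapamil replicate 2. The median was 0.07 without control replicate 3, 0.04 without verapamil replicate 2 and 0.31 without control replicate 2. Ifi35 did not pass without control replicate 1 or verapamil replicate 2 (adjusted p = 0.0768 and 0.0588), and 5 members rose without control replicate 2.

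Antioxidant and mitochondrial genes were higher with verapamil. In the NRF2 oxidative stress list, 19 of 24 rose and 5 did not pass (19 rose and 1, Sod3, fell adjusted over the list alone), with a median of 0.50 (camera adjusted p = 1.20e-08, and adjusted p = 0.0829 with an estimated correlation). The glutathione transferase gene Gstm1 rose from 34.7 ± 6.37 to 83.8 ± 2.61 CPM (1.27 ± 0.12 SE, adjusted p = 3.91e-04). Gsta3 rose from 0.159 ± 0.0456 to 2.13 ± 0.602 CPM (3.68 ± 0.38 SE), and catalase, Cat, rose from 102 ± 17.8 to 219 ± 8.26 CPM (1.09 ± 0.11 SE). Glutathione transferases form families of similar sequence, so reads may be split between members. Nuclear genes of oxidative phosphorylation shifted by small amounts, with 18 of 27 higher and 9 not past the test (21 higher adjusted over the list alone) and a median of 0.22 (camera adjusted p = 7.63e-07, and adjusted p = 0.0829 with an estimated correlation). Ndufa4 rose from 75.9 ± 4.83 to 109.6 ± 6.13 CPM (0.53 ± 0.07 SE) and Cox5a by 0.31. The count was 9 without control replicate 1 and 8 without each verapamil replicate. Macrophage markers rose by a median of 0.58 in the same libraries.

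Lipid genes went both ways, in libraries whose macrophage markers had a median of 0.58. Of 25 genes of cholesterol biosynthesis and uptake, 11 rose, 2 fell and 12 did not pass (12 and 4 adjusted over the list alone), with a median of 0.10. Camera gave adjusted p = 0.0337, and adjusted p = 0.438 with an estimated correlation. Without control replicates 2 and 3 and verapamil replicate 1 it gave 0.0791, 0.0864 and 0.0572. The late-pathway enzyme genes Tm7sf2 (0.99) and Nsdhl (0.70) rose, whereas Hmgcs1, named after its value was seen, fell by 0.39. Without each verapamil replicate 5 genes rose, and without control replicate 2 or 3 the number that fell was 4. Among fatty acid synthesis and SREBP1 targets, 7 of 16 rose, 1 fell and 8 did not pass (8 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.00697, and adjusted p = 0.243 with an estimated correlation). The desaturase genes Fads2, from 39.4 ± 8.38 to 71.8 ± 2.53 CPM, and Fads1 (0.70) rose, and Scd1 (0.89) did except without verapamil replicate 2 (adjusted p = 0.0614). Me1 (-0.25), named after its value was seen, fell, with adjusted p = 0.0676 to 0.103 without control replicate 1 or any 1 of the verapamil replicates. Adipocyte markers went both ways, with 5 of 14 higher, 3 lower and 6 not past the test (6 and 3 adjusted over the list alone), a median of 0.34 and camera adjusted p = 0.0720. Cd36, a fatty acid transporter also made by macrophages, rose from 75.7 ± 19.99 to 207 ± 19.3 CPM (1.45 ± 0.19 SE), and the lipase gene Pnpla2 rose by 0.73. Fabp4 (0.59) and Lipe (0.55), chosen after their values were seen, also rose, Lipe except without control replicate 1 or verapamil replicates 1 or 2 (adjusted p = 0.09998 to 0.120). Pparg, the regulator of adipocyte formation, was at 50.95 ± 6.47 and 64.1 ± 1.08 CPM (0.33 ± 0.09 SE, adjusted p = 0.02502), a call lost without any 1 of the verapamil replicates (adjusted p = 0.0758 to 0.0920). Plin1 (-1.46), which coats lipid droplets, Dgat2 (-0.74) and Plin4 (-0.48, chosen after its value was seen) fell. Plin1 did not pass without control replicates 1 or 3 or any 1 of the verapamil replicates (adjusted p = 0.0730 to 0.149), nor with library totals alone (0.0526) or limma-voom (0.07097), nor Dgat2 without verapamil replicates 1 or 3 (adjusted p = 0.0549 and 0.0530). Counts of adipocyte genes that rose were 3 without verapamil replicate 1 or 2, and camera was at adjusted p = 0.0368 without control replicate 1. Fry called the list higher with all libraries (adjusted p = 0.0464), and the median was 0.23 without control replicate 2.

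Of the other cell types, lymphocytes, mast cells and erythroid cells left few measurable markers. Endothelial markers had 5 of 16 members lower, 1 higher and 10 not past the test (5 and 1 adjusted over the list alone), with a median of -0.28. Camera gave adjusted p = 0.0119, adjusted p = 0.161 with an estimated correlation, and 0.0629 without control replicate 3. Pecam1 fell from 15.8 ± 0.862 to 10.6 ± 0.618 CPM and Plvap from 5.15 ± 0.307 to 2.79 ± 0.229 CPM, and Vwf rose from 3.88 ± 0.193 to 5.75 ± 0.854 CPM except without control replicate 1 or verapamil replicate 2 (adjusted p = 0.0614 and 0.0779). Cdh5 (-0.39) and Tie1 (-0.55), chosen after their values were seen, and Esam (-0.81) fell too. Without any 1 of the verapamil replicates Esam did not pass, nor Tie1 without verapamil replicates 1 or 3 (adjusted p = 0.0611 to 0.0756), which left 3 members lower. Of 3 erythroid and megakaryocyte markers, Pf4 fell from 59.8 ± 7.27 to 27.99 ± 2.18 CPM and Gp1bb fell by 0.86, while Itga2b (-0.35) did not pass. The single lymphocyte marker tested, Cd8a, was at 0.410 ± 0.110 and 0.551 ± 0.224 CPM (adjusted p = 0.480). Among 3 mast cell and basophil markers, Kit was at 9.47 ± 3.15 and 7.35 ± 1.84 CPM (adjusted p = 0.350). Gata2 was at 1.45 ± 0.123 and 0.864 ± 0.218 CPM (adjusted p = 0.0505). It passed as lower with DESeq2 size factors (adjusted p = 0.0497), by limma-voom (0.0453) and with library weights (0.0232), but not by DESeq2. Y-linked genes were measured in all libraries, with a summed level of 232 to 292 CPM. Of the 4 tested, Eif2s3y rose by 0.26, though not without any 1 of the verapamil replicates (adjusted p = 0.0588 to 0.0708). The 32 ribosomal protein genes had a median of 0.03 and 0 past the edgeR test, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2, and the median was -0.06 without control replicate 3 and -0.01 without verapamil replicate 3.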

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

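Counts without rounding and limma-voom with library weights were chosen after the data were seen, and the other alternatives before. The number of genes changed by verapamil (4235, with 2055 genes higher with verapamil and 2180 genes lower with verapamil) was 4226 with DESeq2 size factors, 4268 with upper quartile factors, 4444 with library totals alone, 3980 without a filter, 3841 with the stricter filter, 3896 with DESeq2, 4244 with limma-voom, 4239 without rounding and 5795 with library weights. At an adjusted p under 0.01 it was 1969 (902 higher, 1067 lower), and with a log2 fold change of at least 1 it was 540 (157 higher, 383 lower), as a stricter threshold calls fewer genes. With each library left out in turn it ran from 2236 (without verapamil replicate 2) to 5042 (without control replicate 3), with 1010 to 2452 higher and 1222 to 2590 lower. These fits hold fewer libraries, and why some called more genes was not tested. In each of these settings no gene called among the 4235 was called in the other direction.

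The replicate number as a block gave 2953 genes, 1364 higher and 1589 lower. Deviations from the group mean in same-numbered libraries correlated across genes at 0.00892, -0.167 and -0.127. For differently numbered libraries the range was -0.0619 to 0.155. These values show no pairing by number but are too few to exclude it. The submitters' design text speaks of pairs without saying what is shared, so the block was kept as an alternative. With the block, 11 named genes lost their call, among them Pgk1, Fosl1, Il11, Acta2, Ptprz1, Plin1 and S100a8.

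Of the 30 gene lists, camera called 27. With an estimated correlation 0 were called by camera, where 10 had an unadjusted p under 0.05 and fry called 25. Lists that fry did not call in a direction were glycolysis (adjusted p = 0.135), hypoxia (0.0532), cholesterol (0.0552), stress of the endoplasmic reticulum (0.193) and interferon (0.326), and the cause was not tested. Leaving out 1 library gave 20 lists (without control replicate 3) to 29. For the 141 named genes, 2030 results in the alternatives kept direction and call, 198 kept direction but not the call, and 4 gained it. The pseudocount and the filter for normalised values did not apply, since the table holds counts. At this depth, genes left out by the filter, such as Mlxipl, were not tested.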

Other observations

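Tests of ribosomal protein genes, of macrophage markers that fell, and of hypoxia and glycolysis counts without control replicate 2 were chosen only after the result was seen, as were the gene families described first. Of 153 groups of at least 10 genes that share a symbol stem, 21 passed camera, and with an estimated correlation 0 did by camera, where 9 had an unadjusted p under 0.05. Among the Psmb genes, which encode the β subunits of the proteasome, 8 of 10 rose, with a median log2 fold change of 0.29 (adjusted p = 0.00317, and adjusted p = 0.593 with an estimated correlation). Psmb5 rose from 83.4 ± 0.895 to 106.9 ± 1.12 CPM (SD, n = 3). Of 62 genes with the stem Atp, 27 rose and 7 fell, with a median of 0.23 (adjusted p = 0.00241, and adjusted p = 0.593 with an estimated correlation). That stem mixes pumps of many kinds, which were not tested apart. The proton pump subunits Atp6v1a (0.63), Atp6v1b2 (0.53) and Atp6v1f (0.53), chosen after their values were seen, rose, and the calcium pump Atp2b4 of the plasma membrane fell from 82.3 ± 7.24 to 40.5 ± 1.06 CPM. The sarcoplasmic calcium pump Atp2a3 rose from 14.4 ± 1.40 to 37.4 ± 6.98 CPM. Aldo-keto reductases had 5 of 10 members higher (median 0.41, adjusted p = 0.00861, and adjusted p = 0.593 with an estimated correlation): Akr1a1 (0.38), Akr1b3 (0.45), Akr1b10 (0.50), Akr1c13 (0.84) and Akr1c14 (0.96). Akr1c14 did not pass without control replicate 1 or verapamil replicates 1 or 2 (adjusted p = 0.0597 to 0.0972).

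Among protease families, of 13 Adamts genes 7 fell and 1, Adamts5, rose, with a median of -0.41 (adjusted p = 0.0196, and adjusted p = 0.593 with an estimated correlation). Adamts4, which cleaves aggrecan, fell from 59.6 ± 1.39 to 32.5 ± 1.07 CPM, and Adamts12 fell by 0.91. The Mmp stem had 5 of 15 members lower and 1 higher and did not pass camera (adjusted p = 0.483), nor did the Adam stem, with 2 lower and 3 higher of 15 (adjusted p = 0.626). Of 14 Klf transcription factors 7 fell and 1, Klf15, rose by 0.68, with a median of -0.22 (adjusted p = 0.0254, and adjusted p = 0.593 with an estimated correlation). Klf15 did not pass without control replicate 1 or verapamil replicate 2 (adjusted p = 0.0792 and 0.0794). Klf4 fell from 121 ± 11.8 to 81.0 ± 1.23 CPM and Klf2 fell by 0.81. The medians of the Psmb, Atp, Akr, Adamts and Klf families kept their sign with DESeq2 size factors, upper quartile factors and library totals alone. Other scaling shifts all genes by nearly the same amount, so this was a weak check. These medians also kept their sign without each library in turn. In those fits 6 to 10 Psmb genes rose, and 20 to 29 Atp genes rose and 5 to 9 fell.

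The osteoblast list had a median of -0.95 and the collagen list one of -0.99. Fewer stromal cells would lower all stromal genes alike. However, 46 stromal identity genes outside the matrix had a median of -0.31 (bootstrap interval over genes -0.40 to -0.12), with 21 lower and 1 higher. That argues against fewer stromal cells as the whole cause. Some genes, such as Dlx5, stand on both the stromal and the osteoblast list. Here and below, such intervals resample genes and not libraries. They leave out the spread between libraries and treat the genes as independent. After a trend on transcript length and GC content was taken out, the osteoblast median was -1.02 (-1.15 to -0.61), which argues against such a trend. Ribosomal protein genes had a median of 0.031 (0.0034 to 0.046). TMM scaling itself brings most genes near 0 (median of all tested genes 0.0077), so that value cannot test the scaling. Scaled by library totals alone, the osteoblast median was -0.87. A smaller share of stromal cells as part of the change, and lower expression per cell, may both contribute and stay open.

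Macrophage markers had a median of 0.58. Among 50 myeloid identity genes outside the fixed lists, 49 lay above 0 and 46 rose, with a median of 0.56 (0.49 to 0.61), which is consistent with a larger share of myeloid cells in the verapamil cultures. Lyz2, an abundant transcript of those cells, made up 1.06% to 1.24% of the verapamil counts and 0.407% to 0.635% of the control counts. A larger share of myeloid cells does not account for the 2 macrophage markers that fell, Ccr2 and H2-Ab1. Nor does an even rise of all myeloid genes account by itself for the size of the largest rises. The highest of the 50 genes was at 0.93, below Marco (3.10), Chil3 (2.42), Clec7a (1.89) and Cd5l (1.72). Whether verapamil acted on myeloid growth or survival, or on the loss of other cells, was not tested.

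Hypoxia genes had a median of -1.18 and glycolysis genes one of -0.81, and control replicate 2 was highest in both. Without it the hypoxia median was -0.95 (-1.30 to -0.26), an interval too wide to set that library aside as a cause of the size of the change. Without it 11 of the 19 hypoxia genes passed as lower, Ero1a not among them. That count argues against this library as the whole cause of the calls in the hypoxia list. For glycolysis the median without control replicate 2 was -0.42, and 4 of 20 were lower, from 9 with it. One control library apart from the others may account for part of the glycolysis calls and stays open. Culture density and oxygen at harvest are not given in the labels and were not tested.

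The real grouping of the 6 libraries gave 4235 genes, as large a count in 1 of the 10 splits into 3 and 3, itself. The highest count of the other splits was 0 by edgeR, with 417 genes at an unadjusted p under 0.05 (5803 for the real split) and 3 called by DESeq2 (3896). The splits are too few for a share under 0.05.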
